A study of Arabidopsis thaliana with 12 samples.

How the data were processed

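Roots of Arabidopsis thaliana Col-4 were compared between seedlings given 10 mM NaCl, 1.3 µM Cu, 3 µM Cd or 6 µM Al and control seedlings, per the labels' protocols. Seedlings grew for 10 days in 2% modified MGRL nutrient solution with 200 µM CaCl2 at pH 5.5, at 25 °C and 12 h of light (30 µmol m-2 s-1) per day, and were treated for 24 h. The pH of the treatment is 5.0 in the treatment protocol and 4.5 in the sample descriptions, and which holds is not known here. RNA labelled from 1 µg of total RNA with a Two-Color Quick Amp kit was hybridised to 12 Agilent 4x44K arrays, 3 per stress, each with treated RNA in 1 dye and control RNA in the other. Treated RNA was in Cy5 in replicates 1 and 3 and in Cy3 in replicate 2, per the labels.

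Per the file headers, Agilent Feature Extraction 9.5.1.1 gave each spot a mean signal and a local background median per dye as intensity, a processed signal as intensity after background subtraction and dye normalization, and 0 or 1 flags. Per the file headers, LogRatio is the log10 of red over green processed signal. The deposited value table holds log2 ratios equal to that LogRatio in base 2, with the sign turned for replicate 2 so that treated stands over control. Its columns correlated with the scanner's red over green at r = 1, or -1 in replicate 2, and were not centred. The array build behind the probe annotation is not named in the files. Loci were taken from the array annotation and symbols from a reference table of assembly TAIR10.1, which held 22277 of the 22429 tested loci.

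Ratios were recomputed from mean signals and background medians in limma 3.58.1 (R 4.3.3, statmod 1.5.0, the data.table package, 1.17.8, jsonlite 2.0.0), with normexp background correction at offset 50 and loess within each array, control and outlier spots given no weight. Of 37685 spots that are not controls, 6 to 35 per array were outliers by the scanner's flags and set to missing, which left 64 missing values in 63 tested genes. Spots of the same probe were averaged, and the sign was turned to treated over control. A probe was kept where it stood well above background in the treated or the control channel on at least 3 of 12 arrays and had at least 8 values. Of 37478 probes 28461 passed, and the brightest per locus, or per target name without one, gave 27901 features, called genes here, of which 523 had several probes. They are 22429 loci, 190 of which share their probe with a second locus, and 5472 without a locus. Median spot signals were 174 to 368 in the treated and 156 to 273 in the control channel. Observed over expected log ratios of the spike-in RNAs had slopes of 0.865 to 0.890. In Al, 795 genes were dim in the control channel alone on all 3 arrays and 280 in the treated channel alone, with 523 and 1034 in Cd, 1319 and 254 in Cu, and 1565 and 113 in NaCl.

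limma's lmFit and eBayes fitted all 12 arrays with a coefficient per stress and a dye effect per gene, which left 7 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over 27901 genes per test, with a threshold of 0.05. The dye effect passed for 7878 genes. The 6 pairs of stresses and a moderated F test over the 4 came from the same model. Gene lists, 31 in all, were tested with camera at an inter-gene correlation of 0.01 where at least 3 members were measured, with adjusted p-values over all lists and stresses. Camera with the correlation estimated per list, and fry, were run beside it. The lists cover aluminium tolerance and STOP1-regulated genes, iron, zinc and copper deficiency, copper-replete proteins, ferritins, metal chelation, sulfur, nitrogen, phosphate, sodium and potassium transport, abscisic acid, heat shock, oxidative stress, jasmonate, ethylene, salicylate, auxin, phenylpropanoids, glucosinolates, cell wall, aquaporins, touch, sugar starvation, the clock, 5 sets of tissue markers and reference genes.

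The tests, lists, alternatives and the rule for named genes were written before the data were examined, except where said. Named genes were, among those with a locus, per stress, the 10 that rose and the 10 that fell most with the same sign on 3 arrays, up to 4 called members per list (2 where none passed), the 10 largest of those called in all 4 stresses, and the 10 with the smallest F test p-value. Replicate numbers were checked for pairing before models were blocked. Deviations from stress means of arrays with the same number correlated at r = 0.281 to 0.707. Of 12 arrays, 12 deviated most like 1 of their own number. Numbers were taken as paired, but not in the main model. Number 2 is also the dye swap, so only numbers 1 and 3 separate the 2. Ratio differences between replicates 1 and 3 correlated across stresses at 0.244 to 0.44, and those of the control channel at -0.5 to 0.471. Alternatives were background, normalization, filter, dye term, block, probe, weight, variance and threshold settings, and leaving out each array. Added after the data were seen were a 2-fold threshold, slide as a fixed block, differences within slides and 40 gene families.

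On simulated data over 27901 genes, 78 to 84% of genes changed 1.25-fold per stress were called, 94 to 100% at 1.5-fold, 98 to 100% at 2-fold and 100% at 4-fold, with 0.0289 to 0.065% of unchanged genes. Contrasts of pairs recovered 98 to 99.6% of 2-fold differences, and the F test 90% of changed genes with 0.218% false calls. Of lists of uncorrelated genes, all 4 shifted (also with estimated correlation) and 1 of 120 unshifted passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.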

Results

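The data were log2 ratios of transcript abundance between treated and control roots of Arabidopsis thaliana Col-4 seedlings. Seedlings grew for 10 days in hydroponic culture, and their roots then met 10 mM NaCl, 1.3 µM Cu, 3 µM Cd or 6 µM Al for 24 h. The series title names the question, how roots respond to mild concentrations of different rhizotoxic ions, ions that harm roots. Each of 12 Agilent 2-colour arrays carried labelled RNA of treated roots beside that of control roots, with 3 biological replicates per stress. In replicate 2 of every stress the dyes were swapped.

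Signal covered most of the array. Of 37685 spots that are not controls, 63.5% to 75.6% per array stood well above background in the treated channel and 61.8% to 73.5% in the control channel. The residual SD of the log2 ratio was 0.0607 to 0.117 per array, and the number of arrays limits the precision. Pearson's r across genes between arrays of the same stress was 0.944 to 0.978 in Al, 0.909 to 0.926 in Cd, 0.905 to 0.946 in Cu and 0.284 to 0.513 in NaCl, where genes are not independent replicates. Slide 1 held all Al arrays and Cu replicate 1, slide 2 held Cu replicates 2 and 3 and Cd replicates 1 and 2, and slide 3 held Cd replicate 3 and all NaCl arrays. Values below are fitted log2 treated over control ± SE (n = 3 arrays per stress, variance per gene over all 12). Adjusted p-values come from limma over 27901 features, called genes here, unless a list is named. Of these, 22429 have a locus and 5472 are probes without a locus, which count in all totals but are not named or ranked. List counts are of measured members. A gene is said to have risen or fallen where its adjusted p was under 0.05.

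Al, Cd and Cu changed the root transcriptome widely and NaCl changed it little. After Al, 1227 genes rose and 994 fell at least 2-fold. After Cd, 816 rose and 383 fell, and after Cu 955 rose and 471 fell by as much. After NaCl, 34 genes rose and 31 fell at least 2-fold. Without a fold limit, 16022 genes passed the test in Al (8119 higher, 7903 lower), 14483 in Cd (7360 and 7123), 15901 in Cu (8106 and 7795) and 2582 in NaCl (1526 and 1056). Of these, 1564, 1507, 1687 and 141 were probes without a locus (94, 53, 51 and 0 of those at 2-fold or more). The 2-fold limit and slide as a block were added after the data were seen. NaCl replicates 1, 2 and 3 had ratio SDs of 0.13, 0.222 and 0.244. The NaCl count was 297 without replicate 2 and 572 without replicate 3. It was 4278 with replicate number as a fixed block in place of the dye term and 134 with slide as a block. With slide as a block, 10477 genes passed in Al.

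**Figure D1:**
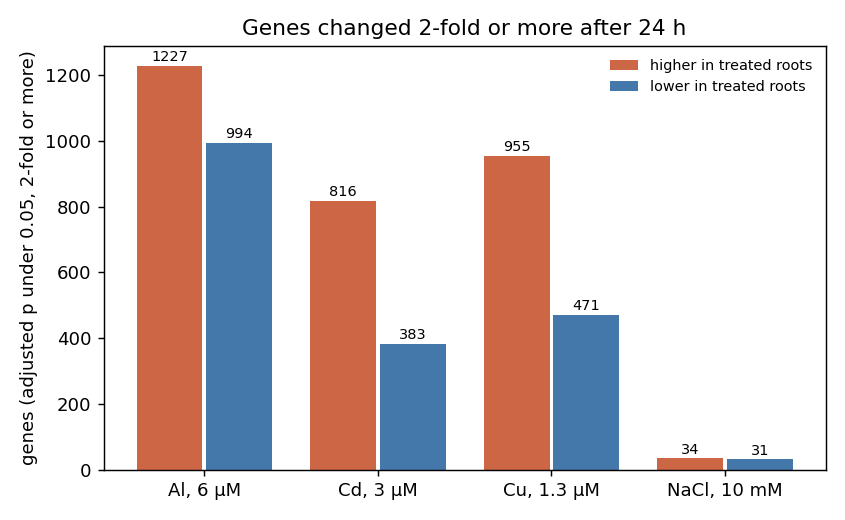
Bars give the number of genes, from 0, that passed the limma test (adjusted p under 0.05) and changed at least 2-fold in each stress, with genes higher in treated roots beside genes lower.

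In Al-treated roots 2 genes of organic acid export rose, and the iron, zinc and copper deficiency lists fell. The lists did not pass with an estimated correlation (adjusted p = 0.41, 0.286 and 0.279). ALMT1 (AT1G08430, 6.34 ± 0.139), the malate channel of Al tolerance, rose 80.9-fold, and MATE (AT1G51340, 3.21 ± 0.0411), a citrate transporter, rose 9.29-fold. FRO2 (AT1G01580, -6.43 ± 0.161), the root ferric-chelate reductase, was the gene that fell most. The root hair markers fell and the abscisic acid and sugar starvation lists rose, but not with an estimated correlation (adjusted p = 0.279, 0.279 and 0.41).

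Among the 10 genes that rose most were AATP1 (AT5G40010, 5.92 ± 0.0939), an AAA-type ATPase, and CEP1 (AT5G50260, 5.71 ± 0.136), a cysteine endopeptidase. The same 10 held the germin-like gene AT5G38910 (6.14 ± 0.0982), the protease inhibitors AT5G43570 (5.76 ± 0.24) and TI1 (AT2G43510, 4.91 ± 0.179), and XTH24 (AT4G30270, 5.45 ± 0.177), a xyloglucan endotransglucosylase. DREB19 (AT2G38340, 5.19 ± 0.084), an AP2-domain transcription factor, DIN2 (AT3G60140, 5.39 ± 0.166), a beta-glucosidase of sugar starvation, and AT1G71140 (4.62 ± 0.173), a MATE family transporter, completed them. Below FRO2, the genes that fell most included UGT74E2 (AT1G05680, -6.26 ± 0.157), a glucosyltransferase, MTPA1 (AT3G61940, -5.80 ± 0.0826), a putative zinc transporter, and AT2G36260 (-5.77 ± 0.205), a putative iron-sulfur cluster assembly gene. MYB72 (AT1G56160, -5.47 ± 0.23) and S8H (AT3G12900, -5.43 ± 0.231), which act in the pathway that makes and secretes iron-mobilising coumarins, fell by similar amounts, as did AT1G12030 (-5.17 ± 0.0837), of unknown function. AT5G33355 (-5.47 ± 0.12) and AT3G59930 (-5.16 ± 0.125) fell too, and their probes list each other's locus, so they are not separate measurements.

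Of the list of aluminium tolerance and STOP1-regulated genes, 17 of 20 rose and 2 fell (list median 1.68, camera adjusted p = 1.98e-08, adjusted p = 0.141 with an estimated correlation). Next to ALMT1 and MATE, NADP-ME1 (AT2G19900, 2.32 ± 0.0506), a malic enzyme, GDH1 (AT5G18170, 2.31 ± 0.0453), a glutamate dehydrogenase, and ALS3 (AT2G37330, 2.04 ± 0.0385), a tonoplast transporter of Al tolerance, rose. Of the iron deficiency list, 2 of 34 rose and 29 fell (list median -2.42, camera adjusted p = 7.39e-12, adjusted p = 0.41 with an estimated correlation). FIT (AT2G28160, -4.76 ± 0.0895), the transcription factor of iron uptake, IRT2 (AT4G19680, -4.19 ± 0.0864), ZIP8 (AT5G45105, -5.70 ± 0.136) and the nicotianamine synthase NAS4 (AT1G56430, -3.51 ± 0.0694) were among those that fell. Of the zinc deficiency list, 1 of 12 rose and 11 fell (list median -1.87, camera adjusted p = 2.98e-07, adjusted p = 0.286 with an estimated correlation). The zinc transporters ZIP5 (AT1G05300, -2.65 ± 0.0606), ZIP9 (AT4G33020, -3.26 ± 0.0761) and ZIP3 (AT2G32270, -2.77 ± 0.0693) fell. Of the copper deficiency list, genes induced when copper is short, 1 of 11 rose and 10 fell (list median -3.36, camera adjusted p = 4.3e-08, adjusted p = 0.279 with an estimated correlation). The iron superoxide dismutase FSD1 (AT4G25100, -4.09 ± 0.0584), the copper regulator CITF1 (AT1G71200, -3.84 ± 0.0597), FRO4 (AT5G23980, -4.07 ± 0.0759) and YSL2 (AT5G24380, -2.56 ± 0.045) fell. Of the copper-replete list, proteins that hold or export copper, 8 of 12 rose and 1 fell (list median 1.23, camera adjusted p = 0.000242, adjusted p = 0.141 with an estimated correlation). The copper/zinc superoxide dismutases CSD1 (AT1G08830, 3.49 ± 0.043) and CSD2 (AT2G28190, 2.76 ± 0.0538) and their copper chaperone CCS (AT1G12520, 1.17 ± 0.0418) rose. In these 5 lists, 19, 32, 12, 11 and 9 members passed adjusted over the list alone.

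Of the abscisic acid and osmotic stress list, 21 of 27 rose and 3 fell (list median 0.69, camera adjusted p = 1.33e-05, adjusted p = 0.279 with an estimated correlation). The homeodomain factors HB12 (AT3G61890, 3.08 ± 0.0981) and HB7 (AT2G46680, 2.08 ± 0.0621) and the factor NAC019 (AT1G52890, 4.39 ± 0.152) rose, and CYP707A3 (AT5G45340, -2.78 ± 0.0618), which breaks down abscisic acid, fell. Of the sugar starvation list, 5 of 6 rose and 0 fell (list median 1.85, camera adjusted p = 0.00382, adjusted p = 0.41 with an estimated correlation). Among them were ASN1 (AT3G47340, 4.56 ± 0.316), an asparagine synthetase, and SEN1 (AT4G35770, 2.28 ± 0.217). Of the heat shock list, 17 of 21 rose and 1 fell (list median 0.47, camera adjusted p = 4.59e-05, adjusted p = 0.365 with an estimated correlation), with HSP17.6C (AT1G53540, 1.97 ± 0.0726) and HSP70 (AT3G12580, 1.12 ± 0.068) higher and HSP23.5 (AT5G51440, -1.56 ± 0.0895) lower. Of the oxidative stress and xenobiotic list, 23 of 34 rose and 8 fell (list median 0.62, camera adjusted p = 0.00517, adjusted p = 0.701 with an estimated correlation). The zinc finger factor ZAT12 (AT5G59820, 11.3-fold) and the glutathione transferase GSTU22 (AT1G78340, 2.70 ± 0.0751) rose, and the transporter DTX3 (AT2G04050, -3.33 ± 0.12) fell. Of the touch and early wound list, 9 of 9 rose and 0 fell (list median 1.06, camera adjusted p = 0.00023, adjusted p = 0.415 with an estimated correlation). Among them were XTH22 (AT5G57560, 3.00 ± 0.108) and TCH3 (AT2G41100, 1.42 ± 0.118). Members that passed adjusted over the list alone numbered 24, 6, 18, 31 and 9 in these 5 lists.

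Of the jasmonate list, 15 of 23 rose and 0 fell (list median 0.37, camera adjusted p = 0.000293, adjusted p = 0.41 with an estimated correlation). Among them were TAT3 (AT2G24850, 3.44 ± 0.157), JAZ10 (AT5G13220, 2.89 ± 0.2) and JAZ7 (AT2G34600, 2.26 ± 0.0492). Of the ethylene list, 10 of 18 rose and 3 fell (list median 0.27, camera adjusted p = 0.0126, adjusted p = 0.577 with an estimated correlation), led by ERF2 (AT5G47220, 2.71 ± 0.0945) and the chitinase CHIB (AT3G12500, 2.19 ± 0.0937). Of the salicylate and defence list, 10 of 22 rose and 2 fell (list median 0.07, camera adjusted p = 0.048, adjusted p = 0.72 with an estimated correlation). NHL10 (AT2G35980, 2.74 ± 0.0668) and ICS1 (AT1G74710, 2.33 ± 0.0983), the isochorismate synthase of salicylate, rose and WRKY53 (AT4G23810, -1.13 ± 0.0419) fell, and the list did not pass with replicate number as a block (adjusted p = 0.054), without background correction (0.059), with median centring (0.0808) or with the strict filter on dim probes (0.0541). Nor did it pass without Al replicate 2 (adjusted p = 0.0598), Cu replicate 3 (0.0597), NaCl replicate 2 (0.0529) or NaCl replicate 3 (0.0535). Of the phosphate list, 12 of 16 rose and 3 fell (list median 0.52, camera adjusted p = 0.0184, adjusted p = 0.494 with an estimated correlation). The ribonuclease RNS1 (AT2G02990, 3.90 ± 0.173) and the galactolipid synthase MGD3 (AT2G11810, 2.18 ± 0.0731) rose, and the transporter PHT1;1 (AT5G43350, -2.15 ± 0.0928), whose family shares sequence, fell. The phosphate list did not pass with the strict filter (adjusted p = 0.0826). Of the aquaporin list, whose members share sequence, 1 of 14 rose and 9 fell (list median -0.65, camera adjusted p = 0.00686, adjusted p = 0.577 with an estimated correlation), with PIP2;4 (AT5G60660, -1.53 ± 0.0373) and TIP1;2 (AT3G26520, -1.30 ± 0.0506) lower and PIP1;4 (AT4G00430, 0.98 ± 0.0614) higher. When adjusted over the list alone, 15, 13, 12, 15 and 10 members of these 5 lists passed.

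In Al the list tests did not pass for sulfate uptake and sulfur deficiency (14 of 22 rose, 4 fell, adjusted p = 0.135) and nitrate and ammonium uptake (4 of 13 rose, 7 fell, adjusted p = 0.199). Nor did the circadian clock (1 of 11 rose, 6 fell, adjusted p = 0.253) and sodium and potassium transport (6 of 13 rose, 3 fell, adjusted p = 0.322). Nor did metal chelation and sequestration (11 of 22 rose, 8 fell, adjusted p = 0.496). In them, the sulfate transporters SULTR1;1 (AT4G08620, -3.42 ± 0.141) and SULTR1;2 (AT1G78000, -2.12 ± 0.0827) fell, the nitrate transporter NRT2.1 (AT1G08090, -2.35 ± 0.0633) fell, the potassium transporter HAK5 (AT4G13420, 3.81 ± 0.0836) rose, the cadmium pump HMA3 (AT4G30120, -3.06 ± 0.121) fell and the metallothionein MT3 (AT3G15353, 1.81 ± 0.0573) rose. Nor did phenylpropanoid synthesis (6 of 18 rose, 11 fell, adjusted p = 0.506) and auxin response (5 of 13 rose, 4 fell, adjusted p = 0.623). Nor did glucosinolate synthesis (1 of 12 rose, 4 fell, adjusted p = 0.72) and cell wall loosening (6 of 13 rose, 5 fell, adjusted p = 0.936). Nor did the ferritins (1 of 3 rose, 1 fell, adjusted p = 0.943). Here the xyloglucan enzyme XTH23 (AT4G25810, 3.15 ± 0.15), the lignin enzyme CCR2 (AT1G80820, 1.52 ± 0.0564) and the auxin-conjugating GH3.1 (AT2G14960, 1.39 ± 0.0665) rose, and the ferritin FER1 (AT5G01600, -0.63 ± 0.0679) fell. The sulfur list passed with replicate number as a block (adjusted p = 0.0467). In Al the medians of the aluminium, iron, zinc and copper deficiency lists with slide as a block were 1.82, -2.02, -1.81 and -3.04.

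In Cd-treated roots the defence and heat shock lists rose, and the glucosinolate, zinc deficiency and iron deficiency lists fell. None of the 5 passed with an estimated correlation (adjusted p = 0.279, 0.279, 0.286, 0.279 and 0.545). BIP3 (AT1G09080, 6.08 ± 0.172), a chaperone of the endoplasmic reticulum, rose 67.6-fold, and the small heat shock protein HSP17.6C rose 17.2-fold. All 12 measured glucosinolate genes fell, with MAM1 (AT5G23010, -2.94 ± 0.0737), which elongates the side chain, lowest of those named. The copper deficiency list, which fell in Al and in Cu, did not pass in Cd.

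The 10 genes that rose most included BIP3 and the germin-like genes AT5G38910 (6.17 ± 0.0982), AT5G39150 (5.61 ± 0.173) and AT5G39180 (4.94 ± 0.169), where the probe of AT5G39150 also lists AT5G39180 and AT5G39110. ARD3 (AT2G26400, 5.77 ± 0.369), an acireductone dioxygenase of methionine salvage, AT5G22555 (5.38 ± 0.119), of unknown function, and AT3G28510 (5.37 ± 0.323), an AAA-type ATPase, rose as well. AT2G30670 (4.54 ± 0.226), a putative tropinone reductase, AT4G19750 (4.46 ± 0.105), a class V chitinase relative, and AT5G43570 (4.38 ± 0.24), a protease inhibitor, completed the 10. AT1G20380 (-5.49 ± 0.0646), a putative prolyl oligopeptidase, fell most. AT5G33355 (-5.13 ± 0.12) with its partner AT3G59930 (-4.76 ± 0.125), S8H (-4.91 ± 0.231), MYB72 (-4.84 ± 0.23), AT2G36260 (-4.77 ± 0.205), AT4G36850 (-4.71 ± 0.131), a PQ-loop protein, FRO2 (-4.64 ± 0.161), ZIP12 (AT5G62160, -4.59 ± 0.186) and MTPA1 (-4.54 ± 0.0826) followed.

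Of the salicylate and defence list, 18 of 22 rose and 0 fell (list median 1.48, camera adjusted p = 1.36e-10, adjusted p = 0.279 with an estimated correlation). ICS1 (3.13 ± 0.0983), ALD1 (AT2G13810, 3.15 ± 0.117), which makes pipecolic acid, NHL10 (2.11 ± 0.0668) and CBP60G (AT5G26920, 1.78 ± 0.0638), a regulator of salicylate synthesis, rose. Of the ethylene list, 17 of 18 rose and 0 fell (list median 0.87, camera adjusted p = 1.88e-08, adjusted p = 0.279 with an estimated correlation). Among them were ERF2 (2.92 ± 0.0945), CHIB (2.90 ± 0.0937) and ERF1 (AT3G23240, 2.37 ± 0.145). Of the heat shock list, 20 of 21 rose and 1 fell (list median 0.96, camera adjusted p = 3.56e-10, adjusted p = 0.279 with an estimated correlation). HSP18.2 (AT5G59720, 2.47 ± 0.0524) and HSP17.4 (AT3G46230, 2.33 ± 0.0769) rose beside HSP17.6C. Of the oxidative stress list, 25 of 34 rose and 4 fell (list median 0.78, camera adjusted p = 3.7e-06, adjusted p = 0.481 with an estimated correlation), with the glutathione transferases GSTF2 (AT4G02520, 2.75 ± 0.13) and GSTF7 (AT1G02920, 1.77 ± 0.106) higher, of which GSTF7 shares sequence with GSTF6. Of the touch and early wound list, 9 of 9 rose and 0 fell (list median 1.28, camera adjusted p = 4.22e-06, adjusted p = 0.386 with an estimated correlation). Among them were TCH3 (2.31 ± 0.118) and MYB15 (AT3G23250, 2.77 ± 0.181). Of the aluminium and STOP1 list, 15 of 20 rose and 2 fell (list median 0.98, camera adjusted p = 7.32e-08, adjusted p = 0.141 with an estimated correlation). ALMT1 (3.71 ± 0.139) and HAK5 (3.32 ± 0.0836) rose. In these 6 lists, 18, 18, 21, 29, 9 and 17 members passed adjusted over the list alone.

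Of the zinc deficiency list, 1 of 12 rose and 11 fell (list median -1.90, camera adjusted p = 6.83e-09, adjusted p = 0.279 with an estimated correlation). ZIP4 (AT1G10970, -3.53 ± 0.0588), ZIP5 (-2.65 ± 0.0606), IRT3 (AT1G60960, -2.34 ± 0.0592) and ZIP1 (AT3G12750, -1.90 ± 0.0511), all zinc transporters, fell. Of the iron deficiency list, 5 of 34 rose and 25 fell (list median -1.44, camera adjusted p = 2.1e-08, adjusted p = 0.545 with an estimated correlation). FRD3 (AT3G08040, -3.01 ± 0.097), the citrate transporter of iron transport to the shoot, FPN2 (AT5G03570, -2.80 ± 0.105) and NAS4 (-1.91 ± 0.0694) fell. Of the ferritin list, 0 of 3 rose and 3 fell (list median -0.56, camera adjusted p = 0.00971, adjusted p = 0.404 with an estimated correlation), FER1 (-1.82 ± 0.0679), FER4 (AT2G40300, -0.56 ± 0.0744) and FER3 (AT3G56090, -0.42 ± 0.0731). Of the copper-replete list, 7 of 12 rose and 2 fell (list median 0.55, camera adjusted p = 0.00653, adjusted p = 0.279 with an estimated correlation), with the laccases LAC12 (AT5G05390, 2.92 ± 0.14) and LAC7 (AT3G09220, 1.84 ± 0.08) and CSD1 (1.31 ± 0.043) higher. Of the glucosinolate list, 0 of 12 rose and 12 fell (list median -1.21, camera adjusted p = 4.85e-10, adjusted p = 0.286 with an estimated correlation), with CYP83A1 (AT4G13770, -2.36 ± 0.0755), BCAT4 (AT3G19710, -2.13 ± 0.0789) and SOT17 (AT1G18590, -1.88 ± 0.0559) lower beside MAM1. Of the phenylpropanoid list, 3 of 18 rose and 11 fell (list median -0.71, camera adjusted p = 0.00732, adjusted p = 0.647 with an estimated correlation). The flavonoid enzymes F3H (AT3G51240, -1.43 ± 0.0376), FLS1 (AT5G08640, -1.22 ± 0.0414) and TT4 (AT5G13930, -1.07 ± 0.0408) fell and CCR2 (1.05 ± 0.0564) rose. This list did not pass with the scanner's own log ratios (adjusted p = 0.0708) or with the deposited value table (adjusted p = 0.075). Members that passed adjusted over the list alone numbered 12, 30, 3, 9, 12 and 14 in these 6 lists.

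Of the aquaporin list, 0 of 14 rose and 12 fell (list median -0.66, camera adjusted p = 2.35e-06, adjusted p = 0.354 with an estimated correlation). Among them were TIP1;2 (-1.23 ± 0.0506), TIP1;1 (AT2G36830, -1.09 ± 0.069) and PIP2;4 (-0.94 ± 0.0373). Of the circadian clock list, 0 of 11 rose and 8 fell (list median -0.28, camera adjusted p = 0.00201, adjusted p = 0.386 with an estimated correlation). Among them were PRR5 (AT5G24470, -0.58 ± 0.0434) and GI (AT1G22770, -0.55 ± 0.06). When adjusted over the list alone, 12 and 8 members of these 2 lists passed. In Cd the list tests did not pass for sugar starvation (4 of 6 rose, 1 fell, adjusted p = 0.104) and sulfate uptake and sulfur deficiency (12 of 22 rose, 6 fell, adjusted p = 0.139). Nor did sodium and potassium transport (7 of 13 rose, 3 fell, adjusted p = 0.194) and abscisic acid and osmotic stress (10 of 27 rose, 5 fell, adjusted p = 0.199). Nor did copper deficiency (2 of 11 rose, 6 fell, adjusted p = 0.419). In them, SULTR1;1 (2.50 ± 0.141), the sulfur deficiency genes SDI1 (AT5G48850, 2.63 ± 0.178) and BGLU28 (AT2G44460, 3.81 ± 0.126), DIN2 (3.69 ± 0.166) and the cation exchanger CHX17 (AT4G23700, 2.69 ± 0.123) rose, the sodium transporter HKT1 (AT4G10310, -1.58 ± 0.131) fell, and the copper transporter COPT2 (AT3G46900, -0.68 ± 0.108) fell. Nor did jasmonate (10 of 23 rose, 6 fell, adjusted p = 0.468) and cell wall loosening (5 of 13 rose, 3 fell, adjusted p = 0.494). Nor did auxin response (7 of 13 rose, 5 fell, adjusted p = 0.611) and phosphate starvation (5 of 16 rose, 2 fell, adjusted p = 0.842). Nor did metal chelation and sequestration (8 of 22 rose, 8 fell, adjusted p = 0.881) and nitrate and ammonium uptake (5 of 13 rose, 6 fell, adjusted p = 0.968). The nitrate transporters NRT2.2 (AT1G08100, 2.41 ± 0.118) and NRT2.4 (AT5G60770, 2.06 ± 0.105) rose, HMA3 (-2.31 ± 0.121) fell, and the phytochelatin synthases PCS1 (AT5G44070, 0.62 ± 0.0345) and PCS2 (AT1G03980, 0.77 ± 0.0411) rose, although the 2 probes of PCS2 gave 0.0818 and 0.758. Without Cd replicate 1 the sulfur (adjusted p = 0.0337) and sugar starvation (0.0475) lists passed in Cd. In Cd the medians of the defence, heat shock, glucosinolate, zinc, iron, aquaporin and clock lists with slide as a block were 1.57, 0.97, -1.28, -1.90, -1.58, -0.68 and -0.28.

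In Cu-treated roots the defence, ethylene and jasmonate lists rose and the copper deficiency list fell. They did not pass with an estimated correlation (adjusted p = 0.279, 0.286, 0.308 and 0.279). ZIP2 (AT5G59520, -4.77 ± 0.0733), a metal transporter, and FSD1 (-4.63 ± 0.0584), the iron superoxide dismutase, were among the 10 that fell most, while CSD1 (3.81 ± 0.043) and CSD2 (3.39 ± 0.0538), the copper/zinc superoxide dismutases, rose 14-fold and 10.5-fold. The pathogenesis-related genes AT4G33720 (6.39 ± 0.178) and AT4G25780 (6.01 ± 0.109) were among those that rose most.

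The germin-like genes AT5G39150 (6.42 ± 0.173), AT5G38910 (5.96 ± 0.0982) and AT5G39180 (5.36 ± 0.169), the dirigent gene DIR5 (AT1G64160, 6.30 ± 0.301) and the glucanase relative AT4G16260 (5.92 ± 0.146) stood beside them. AT2G15780 (5.33 ± 0.14), similar to a blue copper protein, KTI1 (AT1G73260, 5.22 ± 0.146), a Kunitz protease inhibitor, and the peroxidase AT1G49570 (5.20 ± 0.312) completed the 10 that rose most. Besides ZIP2 and FSD1, the largest falls were in MTPA1 (-4.73 ± 0.0826), ZIP12 (-4.65 ± 0.186), AT4G36850 (-4.57 ± 0.131), UGT74E2 (-4.49 ± 0.157), the nicotianamine synthase NAS3 (AT1G09240, -4.31 ± 0.121), FRO4 (-4.15 ± 0.0759), AT5G09570 (-4.09 ± 0.0998), of unknown function, and AT1G20380 (-3.87 ± 0.0646).

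Of the copper deficiency list, 1 of 11 rose and 10 fell (list median -3.02, camera adjusted p = 6.83e-09, adjusted p = 0.279 with an estimated correlation). YSL2 (-3.03 ± 0.045) was among them. Of the copper-replete list, 9 of 12 rose and 1 fell (list median 0.68, camera adjusted p = 0.000154, adjusted p = 0.141 with an estimated correlation). Among them were CCS (1.66 ± 0.0418) and LAC7 (1.53 ± 0.08). Of the zinc deficiency list, 1 of 12 rose and 10 fell (list median -2.01, camera adjusted p = 6.9e-07, adjusted p = 0.306 with an estimated correlation). ZIP4 (-2.59 ± 0.0588), ZIP5 (-2.40 ± 0.0606) and ZIP1 (-2.25 ± 0.0511) fell. Of the iron deficiency list, 5 of 34 rose and 28 fell (list median -1.06, camera adjusted p = 2.3e-06, adjusted p = 0.647 with an estimated correlation). NAS4 (-3.14 ± 0.0694), FRD3 (-2.10 ± 0.097) and the regulator BHLH101 (AT5G04150, -1.99 ± 0.154) fell. Of the aluminium and STOP1 list, 17 of 20 rose and 2 fell (list median 0.81, camera adjusted p = 2.98e-07, adjusted p = 0.141 with an estimated correlation). ALMT1 (3.35 ± 0.139), HAK5 (2.89 ± 0.0836) and the tonoplast malate transporter TDT (AT5G47560, 2.70 ± 0.0829) rose. Of the glucosinolate list, 0 of 12 rose and 10 fell (list median -0.92, camera adjusted p = 1.33e-05, adjusted p = 0.41 with an estimated correlation). Among them were MAM1 (-2.10 ± 0.0737) and CYP83A1 (-1.72 ± 0.0755). In these 6 lists, 11, 10, 11, 33, 19 and 10 members passed adjusted over the list alone.

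Of the salicylate and defence list, 21 of 22 rose and 0 fell (list median 1.16, camera adjusted p = 4.71e-10, adjusted p = 0.279 with an estimated correlation). Among them were NHL10 (3.69 ± 0.0668), ICS1 (2.16 ± 0.0983) and the camalexin enzyme PAD3 (AT3G26830, 2.66 ± 0.0947). Of the ethylene list, 15 of 18 rose and 1 fell (list median 0.90, camera adjusted p = 3.16e-07, adjusted p = 0.286 with an estimated correlation). CHIB (4.18 ± 0.0937), the hevein-like HEL (AT3G04720, 4.13 ± 0.0865) and ERF1 (3.78 ± 0.145) rose. Of the jasmonate list, 17 of 23 rose and 3 fell (list median 1.15, camera adjusted p = 1.43e-06, adjusted p = 0.308 with an estimated correlation), with TAT3 (3.88 ± 0.157), JAZ5 (AT1G17380, 1.88 ± 0.0746) and JAZ8 (AT1G30135, 1.61 ± 0.0641) higher. Of the touch and early wound list, 7 of 9 rose and 0 fell (list median 1.33, camera adjusted p = 0.000115, adjusted p = 0.41 with an estimated correlation). Among them were WRKY40 (AT1G80840, 2.99 ± 0.173) and ZAT12 (1.68 ± 0.0917). Of the sugar starvation list, 5 of 6 rose and 0 fell (list median 2.08, camera adjusted p = 0.00115, adjusted p = 0.386 with an estimated correlation). Among them were DIN2 (4.05 ± 0.166) and ASN1 (3.46 ± 0.316). Members that passed adjusted over the list alone numbered 21, 16, 20, 7 and 6 in these 5 lists.

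In Cu the list tests did not pass for heat shock (12 of 21 rose, 3 fell, adjusted p = 0.102) and phosphate starvation (9 of 16 rose, 3 fell, adjusted p = 0.15). Nor did sodium and potassium transport (6 of 13 rose, 3 fell, adjusted p = 0.199) and metal chelation and sequestration (10 of 22 rose, 6 fell, adjusted p = 0.265). Nor did the circadian clock (3 of 11 rose, 6 fell, adjusted p = 0.322) and oxidative stress (17 of 34 rose, 11 fell, adjusted p = 0.378). In them, the co-chaperone ROF2 (AT5G48570, 1.02 ± 0.0537) and GSTF2 (3.28 ± 0.13) rose, the mitochondrial stress genes UPOX (AT2G21640, -3.35 ± 0.0749) and AOX1A (AT3G22370, -1.84 ± 0.0605) fell, and HMA2 (AT4G30110, -1.09 ± 0.051), a zinc pump, fell. Nor did phenylpropanoid synthesis (3 of 18 rose, 8 fell, adjusted p = 0.452) and nitrate and ammonium uptake (7 of 13 rose, 4 fell, adjusted p = 0.468). Nor did the ferritins (0 of 3 rose, 1 fell, adjusted p = 0.496) and cell wall loosening (6 of 13 rose, 4 fell, adjusted p = 0.595). Nor did sulfate uptake and sulfur deficiency (8 of 22 rose, 8 fell, adjusted p = 0.6) and abscisic acid and osmotic stress (12 of 27 rose, 9 fell, adjusted p = 0.664). Nor did aquaporins (6 of 14 rose, 5 fell, adjusted p = 0.968) and auxin response (6 of 13 rose, 5 fell, adjusted p = 0.975). The factor NAC055 (AT3G15500, 11.3-fold) and the nitrate transporter NRT1.8 (AT4G21680, 2.37 ± 0.122) rose, and RD29A (AT5G52310, -1.41 ± 0.0724), a desiccation-responsive gene, fell. In Cu the medians of the copper deficiency, copper-replete, defence, ethylene, jasmonate and zinc lists with slide as a block were -2.95, 0.73, 1.26, 0.95, 1.24 and -1.97, and that of the auxin list turned from -0.093 to 0.29.

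In NaCl-treated roots few genes changed, with the root hair marker list lower and the salicylate and defence list higher. Neither passed with an estimated correlation (adjusted p = 0.354 and 0.354). XTH26 (AT4G28850, -2.65 ± 0.326), a xyloglucan endotransglucosylase, and AT2G39980 (-2.14 ± 0.109), an acyltransferase family gene, fell. Of the 10 largest rises, those that passed whichever array was left out included PXMT1 (AT1G66700, 1.68 ± 0.214), a methyltransferase, AT1G26380 (1.54 ± 0.163), a berberine-bridge enzyme relative, and GSTF7 (1.51 ± 0.106). The lists of sodium and potassium transport and of abscisic acid and osmotic stress did not move in 1 direction. Fry called both as mixed (adjusted p = 3.03e-06 and 2.12e-06), as it did 119 of all 124 list tests.

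The genes that fell most also held the peroxidases AT1G49570 (-2.47 ± 0.312), AT5G19890 (-2.39 ± 0.287) and AT3G49960 (-1.49 ± 0.127), the arabinogalactan gene FLA6 (AT2G20520, -2.10 ± 0.26), AT5G40590 (-1.61 ± 0.0631), a DC1 domain gene, and AT1G19900 (-1.53 ± 0.146), related to glyoxal oxidase. LON4 (AT3G05790, 1.51 ± 0.157), a Lon protease, and CYP71A12 (AT2G30750, 1.48 ± 0.111), a camalexin enzyme, rose. Other genes among the largest changes lost their call without NaCl replicate 2: PRX52 (AT5G05340, 1.74 ± 0.356), a peroxidase (adjusted p = 0.265), GLIP1 (AT5G40990, 1.72 ± 0.243), a lipase (0.0722), ARD3 (1.61 ± 0.369, 0.404), ASN1 (1.59 ± 0.316, 0.259), AT3G22910 (1.47 ± 0.285), a calcium pump (0.251), RAP2.6 (AT1G43160, -1.96 ± 0.308), an AP2 factor (0.114), and AT3G05950 (-1.61 ± 0.326), germin-like (0.231). All but GLIP1 and RAP2.6 also lost it without NaCl replicate 3. Of 114 named genes that passed in NaCl, 68 lost the call when 1 of the 12 arrays was left out. That number was 10 of 158 in Al, 2 of 159 in Cd and 5 of 161 in Cu.

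Of the salicylate and defence list, 9 of 22 rose and 1 fell (list median 0.40, camera adjusted p = 2.51e-07, adjusted p = 0.354 with an estimated correlation). FMO1 (AT1G19250, 1.37 ± 0.135), PAD3 (0.72 ± 0.0947) and CBP60G (0.62 ± 0.0638) rose. Of the zinc deficiency list, 7 of 12 rose and 1 fell (list median 0.26, camera adjusted p = 3.69e-05, adjusted p = 0.386 with an estimated correlation), with ZIP12 (1.27 ± 0.186) and IRT3 (0.36 ± 0.0592) higher. Of the nitrogen list, 4 of 13 rose and 0 fell (list median 0.22, camera adjusted p = 0.00016, adjusted p = 0.279 with an estimated correlation). NRT2.1 (0.85 ± 0.0633) and the nitrate reductase NIA2 (AT1G37130, 0.42 ± 0.0447) rose. Of the touch and early wound list, 4 of 9 rose and 0 fell (list median 0.34, camera adjusted p = 0.000154, adjusted p = 0.41 with an estimated correlation), with TCH3 (1.40 ± 0.118) highest. Of the aluminium and STOP1 list, 6 of 20 rose and 1 fell (list median 0.11, camera adjusted p = 0.0052, adjusted p = 0.306 with an estimated correlation), with GDH1 (0.38 ± 0.0453) and GDH2 (AT5G07440, 0.55 ± 0.0657) higher. Of the copper-replete list, 5 of 12 rose and 0 fell (list median 0.049, camera adjusted p = 0.0153, adjusted p = 0.279 with an estimated correlation), with the laccase LAC13 (AT5G07130, 0.86 ± 0.0825) higher. Of the oxidative stress list, 9 of 34 rose and 2 fell (list median 0.092, camera adjusted p = 0.00513, adjusted p = 0.701 with an estimated correlation), with GSTF7 and GSTF6 (AT1G02930, 1.35 ± 0.116) higher. Of the sugar starvation list, 2 of 6 rose and 0 fell (list median 0.28, camera adjusted p = 0.0401, adjusted p = 0.577 with an estimated correlation). When adjusted over the list alone, 13, 10, 7, 4, 7, 5, 15 and 3 members of these 8 lists passed.

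Without NaCl replicate 2 the aluminium list (adjusted p = 0.143), the oxidative stress list (0.107) and the sugar starvation list (0.173) did not pass. The sugar starvation list did not pass without NaCl replicate 1 (adjusted p = 0.0674), without Cu replicate 3 (0.0597), with the strict filter (0.194) or with replicate number as a block (0.111) either, and fry called neither it nor the oxidative stress list. In NaCl the medians of the defence, zinc, nitrogen, aluminium, copper-replete and sugar lists with slide as a block were 0.24, 0.11, 0.15, 0.07, 0.10 and 0.032, and those of the touch and oxidative stress lists turned to -0.053 and -0.15. The list tests did not pass for copper deficiency (2 of 11 rose, 0 fell, adjusted p = 0.0503) and aquaporins (3 of 14 rose, 5 fell, adjusted p = 0.102). Nor did heat shock (4 of 21 rose, 1 fell, adjusted p = 0.135) and iron deficiency (4 of 34 rose, 1 fell, adjusted p = 0.17). Nor did cell wall loosening (1 of 13 rose, 3 fell, adjusted p = 0.234) and auxin response (1 of 13 rose, 1 fell, adjusted p = 0.322). Nor did sulfate uptake and sulfur deficiency (0 of 22 rose, 2 fell, adjusted p = 0.345). Of these, copper deficiency (adjusted p = 0.0209), heat shock (0.0189) and aquaporins (0.0182) passed with replicate number as a block, and the median of the iron list, 0.12, was -0.35 with slide as a block. The iron list passed without NaCl replicate 1 (adjusted p = 5.52e-05, mean 0.27 against 0.096) and with median centring (0.0188). Without NaCl replicate 2 the cell wall (0.0189) and aquaporin (0.00419) lists passed, and without NaCl replicate 3 the sulfur list (0.0493). Copper deficiency passed without any 1 of 7 arrays (lowest adjusted p = 0.0223). The aquaporin TIP2;1 (AT3G16240, 0.82 ± 0.0844) rose, and the xyloglucan enzyme XTH14 (AT4G25820, -0.87 ± 0.0899) and the sulfate-activating APS4 (AT5G43780, -0.69 ± 0.0529) fell. Nor did phosphate starvation (1 of 16 rose, 0 fell, adjusted p = 0.345) and the ferritins (0 of 3 rose, 0 fell, adjusted p = 0.356). Nor did the circadian clock (0 of 11 rose, 1 fell, adjusted p = 0.424) and glucosinolate synthesis (0 of 12 rose, 0 fell, adjusted p = 0.496). Nor did jasmonate (1 of 23 rose, 0 fell, adjusted p = 0.651) and abscisic acid and osmotic stress (3 of 27 rose, 3 fell, adjusted p = 0.661). Nor did ethylene (4 of 18 rose, 5 fell, adjusted p = 0.78) and phenylpropanoid synthesis (3 of 18 rose, 4 fell, adjusted p = 0.838). Nor did metal chelation and sequestration (2 of 22 rose, 5 fell, adjusted p = 0.881) and sodium and potassium transport (2 of 13 rose, 2 fell, adjusted p = 0.993). Single members moved: HB7 (0.54 ± 0.0621) rose, the potassium channel SKOR (AT3G02850, -0.79 ± 0.0942) fell, and the ethylene receptors ETR2 (AT3G23150, -1.47 ± 0.19) and ERS1 (AT2G40940, -0.58 ± 0.0439) and the F-box gene EBF2 (AT5G25350, -0.75 ± 0.0727) fell.

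**Figure D2:**
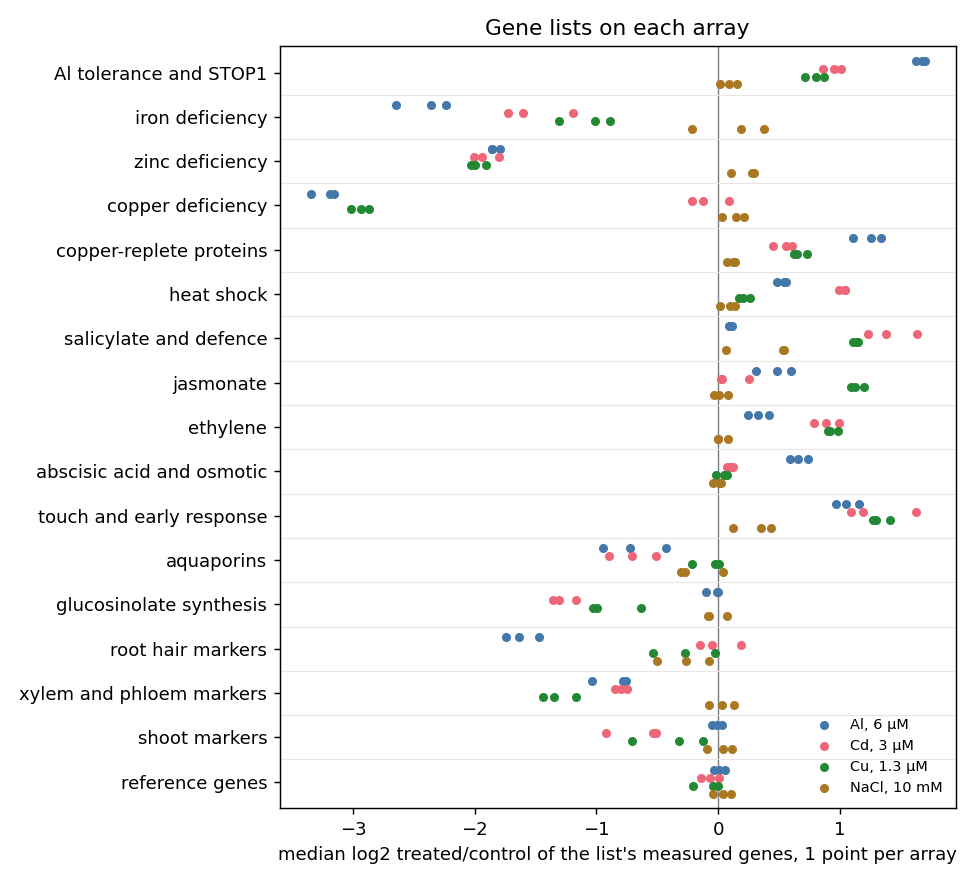
Each point is the median log2 treated over control of a list's measured genes on 1 array (horizontal axis), with 3 arrays per stress and a line for each list. The copper deficiency list has fitted medians of -3.36 in Al and -3.02 in Cu, and -0.22 in Cd and 0.13 in NaCl.

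Markers of cell types within the root moved with the stresses. Of the root hair markers, 0 of 12 rose and 11 fell (list median -1.55, camera adjusted p = 5.74e-07, adjusted p = 0.279 with an estimated correlation) in Al, with EXPA7 (AT1G12560, -2.17 ± 0.074), EXPA18 (AT1G62980, -2.03 ± 0.0889) and RHD2 (AT5G51060, -1.33 ± 0.054) lower. They also passed in NaCl, where 0 of 12 rose and 4 fell (list median -0.26, camera adjusted p = 4.04e-05, adjusted p = 0.354 with an estimated correlation), with RHS19 (AT5G67400, -0.65 ± 0.0906) lower, but not in Cd (3 of 12 rose, 2 fell, adjusted p = 0.936) or Cu (2 of 12 rose, 6 fell, adjusted p = 0.188). Of the xylem and phloem markers, 1 of 8 rose and 7 fell (list median -0.88, camera adjusted p = 0.00316, adjusted p = 0.433 with an estimated correlation) in Al. In Cd, 1 of 8 rose and 7 fell (list median -0.80, camera adjusted p = 0.000755, adjusted p = 0.41 with an estimated correlation), and in Cu, 1 of 8 rose and 7 fell (list median -1.33, camera adjusted p = 0.000993, adjusted p = 0.41 with an estimated correlation). The secondary wall cellulose synthase CESA4 (AT5G44030, -1.69 ± 0.0568) fell in Cu, as it did in Al (-1.17 ± 0.0568) and Cd (-1.01 ± 0.0568), while the phloem sucrose transporter SUC2 (AT1G22710, 1.37 ± 0.0652) rose in Cu. In NaCl these markers did not pass (0 of 8 rose, 0 fell, adjusted p = 0.797). Of the markers of dividing cells, 13 of 16 rose and 2 fell (list median 0.42, camera adjusted p = 0.00262, adjusted p = 0.647 with an estimated correlation) in Al, and 11 of 16 rose and 1 fell (list median 0.20, camera adjusted p = 0.00653, adjusted p = 0.701 with an estimated correlation) in Cd, with CYCA1;1 (AT1G44110, 0.64 ± 0.0541) higher in Al and MCM5 (AT2G07690, 0.36 ± 0.0464) higher in Cd. They did not pass in Cu (9 of 16 rose, 5 fell, adjusted p = 0.16) or NaCl (0 of 16 rose, 0 fell, adjusted p = 0.336). Of the endodermis and suberin markers, 8 of 17 rose and 0 fell (list median 0.14, camera adjusted p = 3.72e-05, adjusted p = 0.41 with an estimated correlation) in NaCl, with the suberin genes FAR5 (AT3G44550, 0.55 ± 0.05) and FAR4 (AT3G44540, 0.55 ± 0.052) higher. They did not pass in Al (8 of 17 rose, 8 fell, adjusted p = 0.938), Cd (7 of 17 rose, 6 fell, adjusted p = 0.856) or Cu (8 of 17 rose, 3 fell, adjusted p = 0.276). Adjusted over the list alone, 12, 8 and 15 of the root hair, vascular and dividing cell markers passed in Al, 8 and 13 of the latter 2 lists in Cd, 8 vascular markers in Cu, and 7 and 8 root hair and endodermis markers in NaCl. With slide as a block, the root hair median was -1.67 in Al and -0.28 in NaCl, the vascular median was -0.72, -0.87 and -1.31 in Al, Cd and Cu, the endodermis median was 0.13 in NaCl, and that of dividing cells was 0.25 in Al, against 0.42, and 0.25 in Cd.

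Photosynthesis genes, used as markers of green shoot tissue, fell in Cd and Cu. Of this list, 0 of 20 rose and 14 fell (list median -0.67, camera adjusted p = 2.14e-06, adjusted p = 0.386 with an estimated correlation) in Cd, and 0 of 20 rose and 16 fell (list median -0.52, camera adjusted p = 0.000186, adjusted p = 0.451 with an estimated correlation) in Cu, while it did not pass in Al (5 of 20 rose, 6 fell, adjusted p = 0.651) or NaCl (4 of 20 rose, 2 fell, adjusted p = 0.661). Adjusted over the list alone, 14 members passed in Cd and 16 in Cu, and with slide as a block the medians were -0.62 and -0.42. The RBCS and LHCB genes share sequence within each family. In Al, LHCB6 (0.64), LHCB4.1 (0.45), PSAD1 (0.68), RBCS1A (0.65) and GAPA (0.20) rose and CA1 (-2.85), PSBR (-0.91), LHCA2 (-0.33), LHCB3 (-0.31), RBCS2B (-0.15) and LHCB2.1 (-0.13) fell. The values of the other members in Al were RBCS1B (-0.16), RBCS3B (-0.092), LHCB1.1 (-0.064), LHCB2.2 (-0.034), LHCB5 (0.18), LHCA1 (-0.18), LHCA3 (-0.098), PSBO1 (-0.19) and RCA (-0.02). In Cd, CA1 (-2.53), LHCB5 (-1.14), PSAD1 (-1.09), LHCA3 (-1.03), PSBO1 (-0.96), LHCB3 (-0.94), LHCA1 (-0.93), RBCS3B (-0.86), PSBR (-0.85), LHCB6 (-0.68), LHCA2 (-0.65), LHCB4.1 (-0.59), RCA (-0.56) and RBCS2B (-0.31) fell, and the others were RBCS1A (-0.19), RBCS1B (-0.56), LHCB1.1 (-0.092), LHCB2.1 (0.048), LHCB2.2 (0.10) and GAPA (-0.13). In Cu, CA1 (-2.60), RBCS1A (-1.32), LHCB5 (-1.08), RBCS3B (-0.78), RBCS1B (-0.75), LHCA1 (-0.73), LHCA3 (-0.69), PSAD1 (-0.66), LHCB3 (-0.63), LHCB6 (-0.55), LHCA2 (-0.49), LHCB4.1 (-0.45), GAPA (-0.35), RCA (-0.31), PSBO1 (-0.25) and RBCS2B (-0.23) fell, and the others were LHCB1.1 (0.10), LHCB2.1 (-0.0041), LHCB2.2 (0.13) and PSBR (-0.021). In NaCl, LHCB6 (0.72), LHCB5 (0.47), LHCB3 (0.37) and CA1 (0.35) rose and RBCS1A (-0.58) and RBCS2B (-0.25) fell, and the others were RBCS1B (-0.47), RBCS3B (-0.65), LHCB1.1 (-0.024), LHCB2.1 (-0.11), LHCB2.2 (0.064), LHCB4.1 (0.15), LHCA1 (0.13), LHCA2 (-0.25), LHCA3 (0.24), PSAD1 (0.23), PSBO1 (0.063), PSBR (-0.14), RCA (-0.18) and GAPA (-0.08).

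Some of these calls rested on few arrays. The sign was not the same on all 3 arrays for RBCS2B and LHCB3 in Al, RBCS3B in Cd, RBCS1B, RBCS2B, LHCA2 and RCA in Cu, and RBCS1A and RBCS2B in NaCl. With replicate number as a block, RBCS2B in Al (adjusted p = 0.336), LHCB2.1 in Al (0.0529), RBCS1A in NaCl (0.136) and RBCS2B in NaCl (0.0598) did not pass, while LHCB1.1 in Cu (0.0182) and LHCA1 in NaCl (0.0478) did. With it as a random block, GAPA in Al did not pass (0.059). When 1 of the 12 arrays was left out, calls were lost (highest adjusted p in brackets) for GAPA (0.705), LHCB2.1 (0.329), RBCS2B (0.232), RBCS1A (0.146), LHCA2 (0.131) and LHCB3 (0.0801) in Al, RBCS3B (0.11) in Cd, PSBO1 (0.477), RBCS1B (0.2), RCA (0.106) and GAPA (0.068) in Cu and RBCS1A (0.502), RBCS2B (0.322), LHCB3 (0.306), CA1 (0.293) and LHCB5 (0.232) in NaCl, these 5 both without NaCl replicate 2 and without NaCl replicate 3.

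The 7 reference genes did not differ from other genes as a list in camera (adjusted p = 0.664, 0.352, 0.317 and 0.136 in Al, Cd, Cu and NaCl). Against no change, fry called them lower in Al, Cd and Cu (adjusted p = 0.000208, 0.00186 and 0.000164) and higher in NaCl (0.0131). In Al, ACT2 (AT3G18780, -0.90 ± 0.0434), an actin, GAPC1 (AT3G04120, -0.39 ± 0.0499) and UBC9 (AT4G27960, -0.13 ± 0.0465) fell and UBQ10 (AT4G05320, 0.30 ± 0.0674) and PP2AA3 (AT1G13320, 0.11 ± 0.0328) rose. UBC9 in Al fell without the same sign on all arrays and did not pass without Al replicate 1 (adjusted p = 0.169), Al replicate 3 (0.122) or Cd replicate 2 (0.055), and its value was 0.08 with median centring in place of loess. PP2AA3 did not pass without Al replicate 1 or 2 (adjusted p = 0.0516 and 0.0742). In Cd, GAPC1 (-0.37 ± 0.0499), UBQ10 (-0.37 ± 0.0674) and ACT2 (-0.20 ± 0.0434) fell, and TIP41 (AT4G34270, 0.092 ± 0.0356) rose but did not pass with replicate number as a block (adjusted p = 0.0572) or without 1 of 10 arrays (up to 0.165). In Cu, GAPC1 (-0.83 ± 0.0499), UBC9 (-0.28 ± 0.0465) and ACT2 (-0.18 ± 0.0434) fell, although ACT2 turned to 0.23 in Cu with median centring. The values that did not pass were SAND (0.028) and TIP41 (0.054) in Al, SAND (0.06), PP2AA3 (-0.015) and UBC9 (-0.033) in Cd, UBQ10 (0.0058), PP2AA3 (0.047), SAND (0.011) and TIP41 (0.021) in Cu, and UBQ10 (0.13), UBC9 (0.077), ACT2 (0.071), PP2AA3 (0.029), SAND (0.031), TIP41 (0.051) and GAPC1 (0.048) in NaCl.

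Over 31 lists and 4 stresses, 58 of 124 camera tests passed with the preset correlation and 0 passed with an estimated correlation, where limma's fry gave 81 directional and 119 mixed calls. Mean and median of a list differed in sign in 11 tests, none of them called, and the camera direction differed from the sign of the median in none of the called lists.

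Some list members moved in opposite directions in different stresses. SULTR1;1, the high-affinity sulfate transporter, fell in Al (-3.42) and rose in Cd (2.50) and Cu (1.16), with adjusted p of the difference 1.39e-09 and 7.65e-09. The osmotic stress factor HB7 (2.08 in Al, adjusted p of the difference from Cu 6.25e-10) and the glutathione transferase GSTU22 (2.70 and -1.87, 1.7e-10) rose in Al and fell in Cu, as did the oxophytodienoate reductase OPR1 (1.21 and -1.32, 2.92e-08). ACS2, an ethylene synthesis gene, fell in Al (-1.02) and rose in Cu (1.30, 1.14e-07). ETR2 fell in NaCl and rose in Cd (1.08, 1.8e-05) and Cu (1.30, 6.61e-06). OPR1, ACS2 and the values of GSTU22 in Cu and ETR2 in Cd and Cu were chosen after they were seen, as list members that passed with at least 2-fold changes in opposite directions.

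In limma contrasts, 11806 genes between Al and Cd (1871 by 2-fold or more) differed, 12711 genes between Al and Cu (2115 by 2-fold or more), 13199 genes between Al and NaCl (2025 by 2-fold or more), 8462 genes between Cd and Cu (708 by 2-fold or more), 10831 genes between Cd and NaCl (1194 by 2-fold or more) and 12617 genes between Cu and NaCl (1451 by 2-fold or more). Pearson's r across genes was 0.573 for Al and Cd, 0.537 for Al and Cu, 0.747 for Cd and Cu, and 0.244, 0.234 and 0.165 for Al, Cd and Cu with NaCl. They carry no p. Each slide that held both stresses of a pair gave the difference within it: 9517 genes between Al and Cu on slide 1, 6207 between Cu and Cd on slide 2 and 6888 between Cd and NaCl on slide 3. Slide 1 held only 1 Cu array and slide 3 only 1 Cd array, so there the lone array was assumed to vary like the other groups. The other pairs share no slide. With slide as a block, 6139 genes differed for Al and Cd, and 4886, 6891 and 5442 for Al, Cd and Cu with NaCl.

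Between lists, the copper deficiency list lay lower in Al than in Cd (median difference -2.68, adjusted p = 4.34e-10, adjusted p = 0.24 with an estimated correlation) and lower in Cu than in Cd, given as Cd minus Cu (median difference 2.78, adjusted p = 5.41e-14, adjusted p = 0.24 with an estimated correlation). The iron deficiency list lay lower in Al than in Cu (median difference -1.07, adjusted p = 1.36e-09, adjusted p = 0.501 with an estimated correlation). The zinc deficiency list lay lower in Cd than in NaCl (median difference -2.24, adjusted p = 2.06e-10, adjusted p = 0.24 with an estimated correlation). The root hair markers lay lower in Al than in Cd (median difference -1.63, adjusted p = 9.39e-09, adjusted p = 0.24 with an estimated correlation). The heat shock list lay higher in Cd than in Cu, as Cd minus Cu (median difference 0.91, adjusted p = 4.34e-10, adjusted p = 0.24 with an estimated correlation), and the jasmonate list lower (median difference -0.68, adjusted p = 4.34e-10, adjusted p = 0.24 with an estimated correlation). Of 186 such tests over the 6 pairs, 88 passed with the preset correlation, and the smallest adjusted p with an estimated correlation was 0.240.

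The moderated F test over the 4 stresses passed for 18515 genes (66.4%), of which 3852 spanned at least 2-fold. Its 10 smallest p-values held the metal genes CSD1, FSD1, ZIP2, YSL2, MTPA1 and MATE, the peptidase AT1G20380, the MATE family gene AT1G15180, the kinase AT5G59680 and BCA3. CSD1 was 3.49 in Al, 1.31 in Cd, 3.81 in Cu and -0.013 in NaCl. MATE, the citrate transporter, was 3.21, 0.59, 0.43 and -0.048 in the same order. BCA3 (AT1G23730, 1.05 ± 0.0565), a beta carbonic anhydrase, rose least in Al, more in Cu (3.35 ± 0.0565) and most in Cd (4.20 ± 0.0565).

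**Figure D3:**
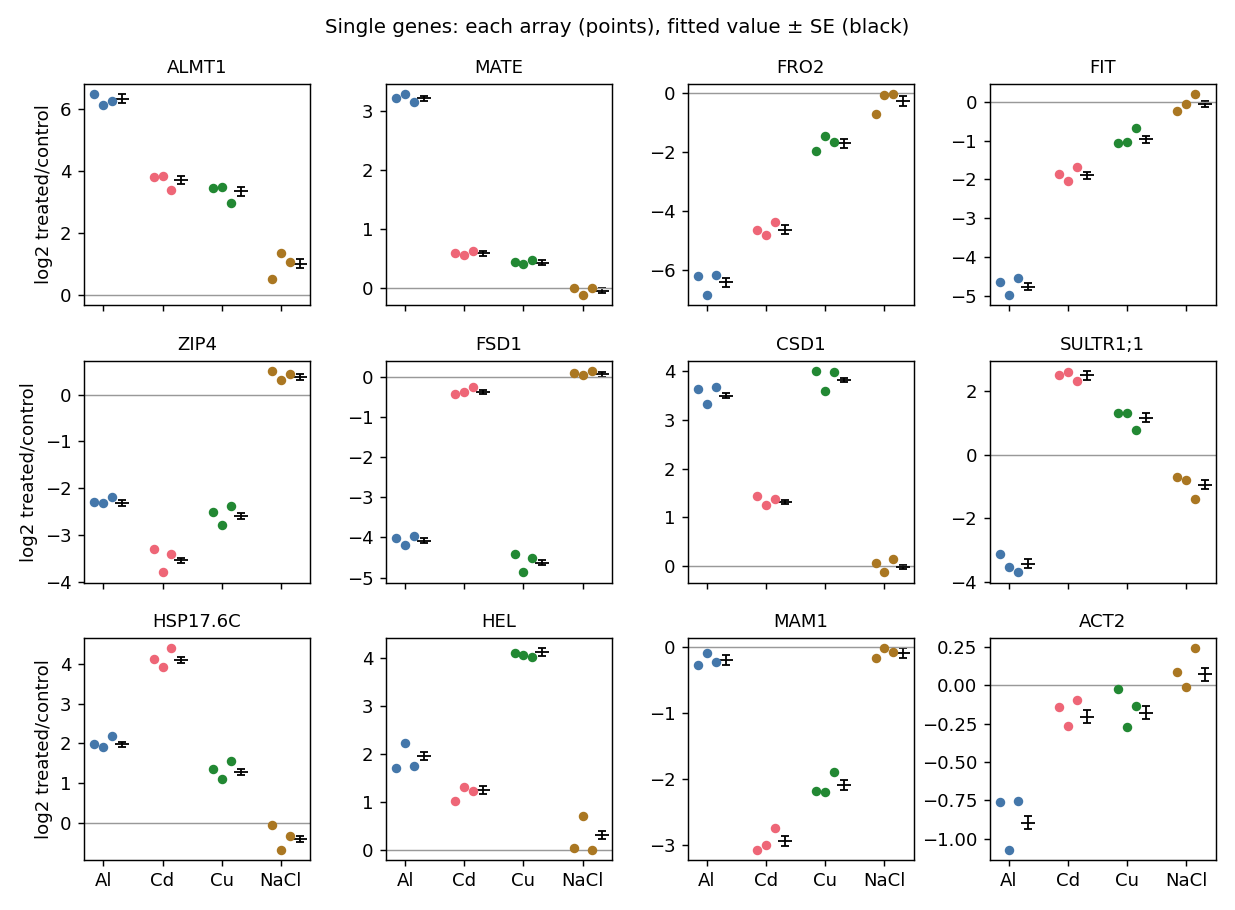
Points give log2 treated over control of 12 genes on each array (vertical axis, its own scale per gene). Black marks give the fitted value ± SE per stress (n = 3 arrays, variance over all 12).

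Al, Cd and Cu shared a large response. At 2-fold or more, 333 genes rose and 136 fell in all 3, where independent lists would share 1.23 and 0.23. For pairs, 437 rose in both Al and Cd (expected 35.9), 431 in Al and Cu (42) and 506 in Cd and Cu (27.9), and 207, 219 and 218 fell (expected 13.6, 16.8 and 6.46). Across all 4 stresses, 764 genes passed in 1 direction, 501 higher and 263 lower, where independence gives 55.4, and 13 rose at least 2-fold while 0 fell by as much (limma). Among the 764, ALMT1, AATP1, PRX52, AT3G22910, AT3G28510, ARD3, DIR5, AT5G22555, AT5G39150 and ASN1 had the largest mean change. PRX52 rose in Al (4.45 ± 0.356), Cd (3.26 ± 0.356), Cu (4.72 ± 0.356) and NaCl (1.74 ± 0.356). AT5G39150 in Al (0.71 ± 0.173) did not pass without Al replicate 2 (adjusted p = 0.0914), and all 10 lost their call in NaCl without NaCl replicate 2 (PRX52 0.265, DIR5 0.365, ALMT1 0.0655), and all but ALMT1 without NaCl replicate 3. Without NaCl replicate 2 the 764 became 99 and without NaCl replicate 3 they became 207, and the count was 1200 with replicate number as a block and 31 with slide as a block.

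Each array had its own control channel, and whether the stresses shared control RNA is not stated. In 20 simulations in which the 4 stresses shared controls and no gene changed, r between stresses was 0.537 with a covariance of 0.00224, against observed covariances of 0.176 for Al and Cd, 0.179 for Al and Cu, 0.195 for Cd and Cu, and 0.0244, 0.0184 and 0.014 for these with NaCl. As no gene changed there, 0 called in all 4 stresses (limma) was fixed in advance. Shared controls may add to the excess over independent lists. Genes called in opposite directions numbered 2030 for Al and Cd, 2458 for Al and Cu and 870 for Cd and Cu, of which 27, 38 and 2 changed at least 2-fold in both.

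**Figure D4:**
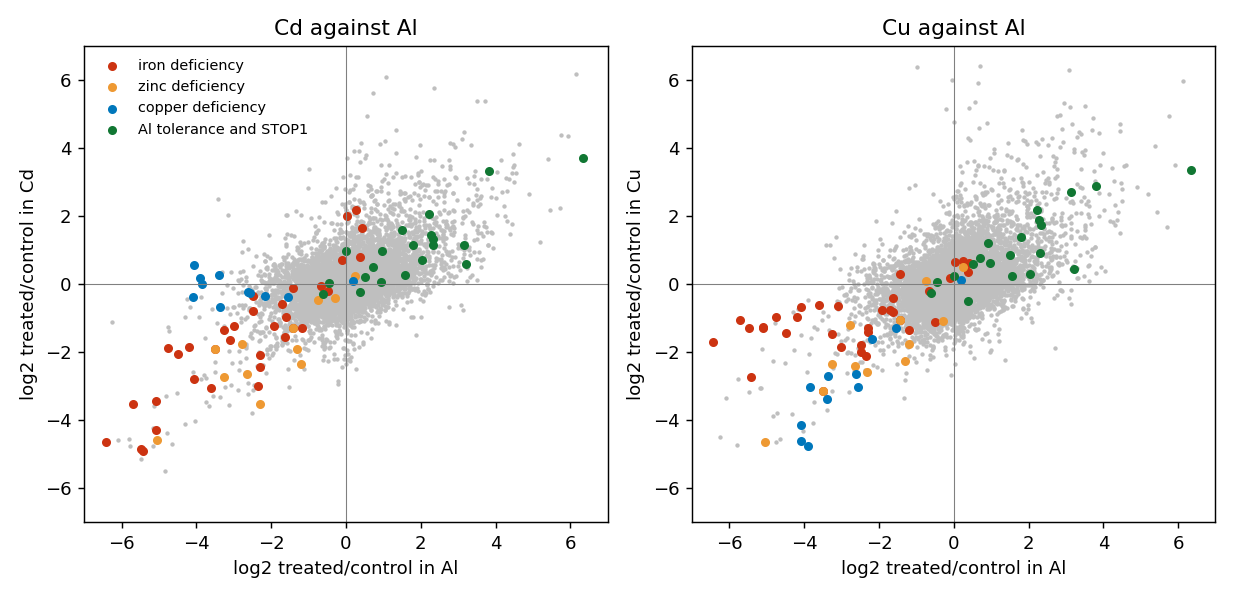
Each point is a gene, with its fitted log2 treated over control in Al on the horizontal axis and in Cd (left) or Cu (right) on the vertical axis, and colours mark 4 gene lists.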

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

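Of the tests of explanations below, those of copper carried by the Al treatment and of the control roots were chosen before their results were seen, and the tests of a mislabelled array, the slide, root hair cells, noise and ratio range, and the splits of the arrays, only after.

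These results stood out because a stress and NaCl moved a gene or list in opposite directions, both past the threshold, with a limma test of the difference itself. The zinc deficiency list differed from NaCl by a median of -2.15 for Al (adjusted p = 2.74e-08, and 0.277 with an estimated correlation), -2.24 for Cd (adjusted p = 2.06e-10, and 0.24 with an estimated correlation) and -2.31 for Cu (adjusted p = 2.18e-08, and 0.277 with an estimated correlation). The metal transporter ZIP12 differed from NaCl by -6.31 for Al (adjusted p = 3.92e-09), -5.86 for Cd (adjusted p = 2.3e-08) and -5.91 for Cu (adjusted p = 1.46e-08). The PQ-loop gene AT4G36850 (1.18 in NaCl) differed by -5.83 for Al (adjusted p = 5.61e-10), -5.89 for Cd (adjusted p = 1.69e-09) and -5.75 for Cu (adjusted p = 1.49e-09), and the Lon protease LON4 by -3.40 for Al (adjusted p = 1.51e-07), -3.32 for Cd (adjusted p = 4.6e-07) and -3.56 for Cu (adjusted p = 2.12e-07). These genes fell in Al, Cd and Cu and rose in NaCl.

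Other genes rose in 1 or more metals and fell in NaCl. The peroxidase AT1G49570 differed from NaCl by 5.57 for Al (adjusted p = 7.82e-07), 4.28 for Cd (adjusted p = 1.5e-05) and 7.67 for Cu (adjusted p = 1.09e-07). The peroxidase AT5G19890 differed by 5.04 for Al (adjusted p = 9.17e-07), 3.74 for Cd (adjusted p = 2.23e-05) and 6.16 for Cu (adjusted p = 3.27e-07), and the putative tropinone reductase AT2G30670 (-1.24 in NaCl) by 2.59 for Al (adjusted p = 3.29e-05), 5.78 for Cd (adjusted p = 1.1e-07) and 4.61 for Cu (adjusted p = 4.8e-07). The germin-like AT3G05950 differed by 4.14 for Al (adjusted p = 1.38e-05) and 5.71 for Cu (adjusted p = 1.54e-06), and the AP2 factor RAP2.6 by 3.88 for Cu (adjusted p = 2.01e-05). Without NaCl replicate 2, AT3G05950 (adjusted p = 0.231), RAP2.6 (0.114) and AT2G30670 (0.125) did not pass in NaCl itself, nor did AT3G05950 (0.0989) and AT2G30670 (0.0525) without NaCl replicate 3.

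The copper deficiency list fell in Al as in Cu, in neither with an estimated correlation (adjusted p = 0.279 and 0.279). A mislabelled Al array is argued against by the lowest r across genes among Al arrays, 0.944, against 0.565 as the highest of an Al with a Cu array. For Cu, the slide of all Al arrays is argued against by list medians of -2.94 on it (replicate 1) and -3.02 and -2.87 off it. For Al it stays open. Copper carried by the Al treatment may explain the pattern and stays open: of genes outside the copper lists that changed 2-fold in Cu and under 0.5 on the log2 scale in Cd, 74.6% moved in Al in the Cu direction, but so did 73.9% of genes that changed 2-fold in Cd and under 0.5 on the log2 scale in Cu in the Cd direction. Pearson's r with Al was 0.356 over the Cu set and 0.534 over the Cd set. This cannot decide, as the sets hold different genes (327 and 165). A biological response to Al stays open as well, untested.

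The iron and zinc deficiency lists fell in Al, Cd and Cu, though not with an estimated correlation (adjusted p = 0.41, 0.545 and 0.647 for iron, 0.286, 0.279 and 0.306 for zinc). In NaCl neither fell, but the iron median (0.12) was -0.35 with slide as a block, where only Cd replicate 3 links NaCl. Higher levels in the control roots of the metal arrays are argued against by median control-channel differences from the NaCl arrays of 0.118 for the iron list (interquartile range 0.213) and 0.213 for the zinc list (0.307). Fewer root hair cells are argued against in Cd and Cu by root hair marker medians of 0.011 and -0.25 (interquartile ranges 0.431 and 0.458), above both lists' falls by more than that range. In Al the marker median was -1.55 (0.822), so fewer such cells may explain part of the falls. A response to the metals may remain as a hypothesis, found and tested on the same data.

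NaCl changed fewer genes, and by less. Noise that hides changes of ordinary size is argued against by the 69 genes at 2-fold or more in NaCl, called or not, against at least 1199 in each other stress. A narrow range of ratios on the NaCl slide is argued against by Cd replicate 3 on that slide, whose spread was 1.04 times that of the other Cd arrays. A milder dose of NaCl than of the metals was not tested.

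Other splits of the arrays were counted for each result. For the stresses, 4 splits are too few for a share under 0.05, and 1 of 4, the real one, gave as many genes: 16022 in Al (highest other 1), 14483 in Cd (0), 15901 in Cu (0) and 2582 in NaCl (0). For pairs, 10 splits are too few as well, with 11806, 12711, 13199, 8462, 10831 and 12617 genes for Al and Cd, Al and Cu, Al and NaCl, Cd and Cu, Cd and NaCl, and Cu and NaCl, and 0 as the highest other of each. The F test (18515, highest other 5179, 1 of 100 splits as large) argues against chance, but not against slide. For genes called in 1 direction in all 4 stresses (764, highest other 0) chance is left open, since a swap fixes the outcome, with at most 1 called gene in its stress. The list calls (58, highest other 54) had 1 of 100 splits as large, but the count hardly changed with the split and was 0 with an estimated correlation, so chance is left open for them.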

How the results depend on the processing

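The 2-fold threshold, slide as a fixed block and the differences within slides were chosen only after the data were seen, and the other alternatives before. The cause of a change was not tested unless named.

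Of the 13 counts, those for Al, Cd and Cu, the F test and the pairs stayed within 1.5 times their values under all planned settings except the 1.5-fold threshold. Named genes kept side and direction in 576 to 658 of 658 results over the settings without a fold threshold or a left-out array (602 under the strict filter, which tested no others), and lists in 117 to 124 of 124, or 66 with an estimated correlation and 97 with fry. The loess with Aquantile setting leaves ratios unchanged and so tests nothing. The share of higher genes in Al, Cd and Cu (50.7%, 50.8% and 51%) was 62.7%, 55.5% and 60.8% with median centring in place of loess and 46.7%, 43.3% and 44.1% with the scanner's LogRatio, so the larger side depends on the normalization. Each stress fitted alone gives no F test or pair values.

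The NaCl count, 2582, was 4485 without background correction, 4171 with the scanner's LogRatio, 4184 with the deposited table, 1577 with median centring, 1169 without a dye term, 292 fitted alone with 2 residual degrees of freedom, and 4157 at adjusted p under 0.10. The count for all 4 stresses, 764, was 1237, 1178, 1180, 466, 378, 112 and 1208 in the same order, and 1709 at an unadjusted p under 0.05 in each.

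A fold threshold leaves fewer genes by construction. At 1.5-fold the counts were 4619 in Al, 2879 in Cd, 3593 in Cu, 313 in NaCl, 100 in all 4, 7911 for the F test, and 4009, 4600, 4392, 2062, 2879 and 3671 for Al and Cd, Al and Cu, Al and NaCl, Cd and Cu, Cd and NaCl, and Cu and NaCl. At 2-fold they were 2221, 1199, 1426, 65, 13, 3852, and 1871, 2115, 2025, 708, 1194 and 1451. The share of higher genes at 2-fold was 68.1% in Cd (50.8% without) and 67% in Cu (51%).

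With replicate number as a fixed block, which replaces the dye term, the paired counts were 4278 in NaCl and 1200 in all 4 stresses. It changed no other count's side, and lists and genes it changed are given with them. With slide as a fixed block, 10477 genes passed in Al, 31 in all 4 and 134 in NaCl (35.1% higher, against 59.1%). Only Cd replicate 3 links NaCl to other slides. Pairs gave 6139 for Al and Cd, and 4886, 6891 and 5442 for Al, Cd and Cu with NaCl. As random blocks, replicate number and slide had consensus correlations of 0.137 and -0.0474.

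Leaving out each array in turn gave 13553 to 16337 genes in Al, 10467 to 14879 in Cd, 13052 to 16014 in Cu, 297 to 3579 in NaCl, 99 to 1035 in all 4, 17121 to 18450 for the F test, 9780 to 12186 for Al and Cd, 10985 to 12835 for Al and Cu, 11592 to 13594 for Al and NaCl, 6403 to 8530 for Cd and Cu, 8315 to 11318 for Cd and NaCl, 10757 to 12804 for Cu and NaCl, and 56 to 61 list calls.

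List calls fell from 58 to 0 with an estimated correlation, while fry called 81. Reversed were ACT2 in Cu (0.23) and UBC9 in Al (0.080) with median centring, and the nitrogen list in Cd with fry (mean 0.24). Signal over background limits the faintest genes, as 61.8% to 75.6% of spots per channel stood well above it.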

Other observations

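The tests of gene families below were all chosen only after the results were seen. Of 160 tests of 40 families, 32 passed in limma's camera and 0 with an estimated correlation.

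Proteasome subunits rose in the metals: 60 of 64 rose and 3 fell in Al (median 0.83, camera adjusted p = 2.28e-20, and adjusted p = 0.0721 with an estimated correlation), 49 of 64 rose and 3 fell in Cd (median 0.21, camera adjusted p = 2.62e-07, and adjusted p = 0.422 with an estimated correlation) and 54 of 64 rose and 4 fell in Cu (median 0.27, camera adjusted p = 7.32e-09, and adjusted p = 0.384 with an estimated correlation).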
